A study of Mus musculus with 6 samples.

How the data were processed

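RNA was measured by bulk RNA sequencing in 6 subcutaneous CT26 tumours, 3 from mice given irinotecan and 3 from mice given solvent. CT26 is a mouse colon carcinoma cell line that grows in BALB/c mice. Irinotecan is a prodrug of a topoisomerase I inhibitor. Per the labels' protocols, mice were randomized once tumours had grown to 100 mm3, and the drug was given intraperitoneally at 25 mg/kg every 4 days. Tumours were frozen, total RNA was extracted with Trizol and its integrity was checked on a Bioanalyzer. The time from the last dose to collection is not given in the sources used here. The series text speaks of duplicates, whereas the labels list 3 samples per group, and all 3 were used. The labels do not say that each sample came from a separate mouse, so p-values measure the spread between these samples.

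Per the submitters' processing notes, the tools were CASAVA, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, with the genome build GRCm38 (mm10). The notes give no role for each tool, and the annotation release and the strand setting are not given in the sources used here. The authors deposited 1 table of 25251 genes. Its library columns hold a normalized signal, that is, read counts per gene divided by 1 factor per library. This was read from the deposited values: within each library 100% of the values were whole multiples of the smallest non-zero value, at a tolerance of 1e-06. Whole reads were therefore recovered by division. The table also holds the authors' mean signal per group, the authors' log2 fold changes, and the authors' unadjusted and adjusted p-values, per the file headers. The deposited adjusted p-value is 1 for 11267 genes, which includes 7 genes without an unadjusted p-value. The recovered reads per library ranged from 13940650 to 15656894. Reads without molecular identifiers are not independent molecules, so depth bounds counting error only. Without a stated strand setting, reads from overlapping antisense genes cannot be told apart, and genes with near-identical copies, such as ribosomal protein pseudogenes and granzymes, may share reads.

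Because the table holds no raw counts, the planned edgeR test on counts gave way to the planned substitute for normalized values. This was limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, on log2(normalized count + 1). Fold changes are on that scale, which understates the change of low genes. Genes with a mean normalized count of at least 10 over the 6 libraries were tested, which left 14639. The model held the group only, and genes with a Benjamini-Hochberg adjusted p-value under 0.05 were called.

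Before the data were examined, 40 gene lists were fixed for immune cells, interferon responses, stroma, drug response, stress, metabolism and tissues that a tumour sample could hold. Lists with at least 5 tested members were compared with the other genes by camera, with an inter-gene correlation preset at 0.01, two-sided, and adjusted over the lists tested. Camera with an estimated correlation and fry were alternatives. The rule for named genes was fixed at the same time. It takes, from protein-coding genes whose 3 irinotecan libraries all lie on one side of the 3 controls, the genes past the threshold with the largest change, or, where none pass, the 4 with the smallest unadjusted p in each direction. It adds the 3 members with the smallest unadjusted p in each list described in detail (1 such gene is not reported here), and a fixed panel of Top1, Cd8a, Gzmb, Ifng, Cxcl9, Cd274, Cdkn1a and Mki67. The 13 lists described in detail were chosen after their p-values were seen: the 10 with the smallest camera p, and the lists for MHC class I, T cells and p53 targets.

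Alternatives planned beforehand were quantile normalization, other pseudocounts, no low-value filter, protein-coding genes only, other thresholds, the replicate number as a block, each library left out in turn, members of a single list only, and DESeq2 1.42.0, limma-voom and edgeR 4.0.16 with DESeq2-type size factors on the recovered reads. After the data were seen, edgeR with TMM, edgeR and DESeq2 without irinotecan replicate 1, limma with estimated library weights, and removal of a smooth trend on GC content and gene length were added. GC content was the median over a gene's transcripts in GENCODE M21, and 99.86% of genes had a value. A planned filter at a mean count of 10 coincides with the filter used.

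The tests were first run on simulated counts for the same 14639 genes, with the observed means, library sizes and dispersions, and 200 genes changed. Each gene was drawn independently, with 1 dispersion for all 6 libraries. The added spread of irinotecan replicate 1 was thus shared by every library, and genes that vary together were not simulated. For irinotecan against control, limma recovered 2.99% of the genes changed 1.5-fold, 34.3% of those changed 2-fold and 80.3% of those changed 4-fold, and 4 of its 82 calls were unchanged genes. DESeq2 recovered 19.4%, 50.7% and 84.8% at those sizes, and 25 of its 128 calls were unchanged genes. With the dispersions of the libraries other than irinotecan replicate 1, limma recovered 32.8%, 67.2% and 87.9% and DESeq2 40.3%, 67.2% and 86.4%, and 6 of 131 and 14 of 143 calls were unchanged genes.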

Results

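Gene expression was measured by RNA sequencing in 6 subcutaneous CT26 tumours, 3 treated with irinotecan and 3 with solvent, to ask how the drug alters expression in the tumour, immune genes included. The libraries held 15656894, 13940650 and 15366073 recovered reads for control replicates 1, 2 and 3, and 15083538, 15195613 and 14001328 for irinotecan replicates 1, 2 and 3. Same-group libraries differed by more than counting noise, with a chi-square per degree of freedom of at least 10.75, so none was counted as a duplicate.

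Irinotecan replicate 1 stood apart from the other 5 libraries. Its log2 values correlated with theirs at 0.9324 to 0.9406 across genes, against 0.9748 to 0.9846 for the 10 other pairs. It had reads for 19040 genes, whereas the others had reads for 20571 to 21426, and 544 of its genes had a single read, against 1391 to 1692. Genes above 60% GC had a median log2 difference from the control mean of -0.76 in it. Genes over 8000 bases, by the deposited gene length, had one of 0.36. Cd8b1, a chain of the CD8 co-receptor, and the chemokine Ccl5 had 0 reads in this library, while their normalized counts in the other 5 were 41.6 to 70.3 and 29.0 to 111.5. Both genes were singled out after their values were seen. The same holds for the Y-linked gene Eif2s3y, which had 0 reads in this library and 95.1 to 155.1 normalized counts in the others. Cd8a, the gene of the other CD8 chain, had 95.5 normalized counts in this library, against 114.3 to 198.4.

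**Figure D1:**
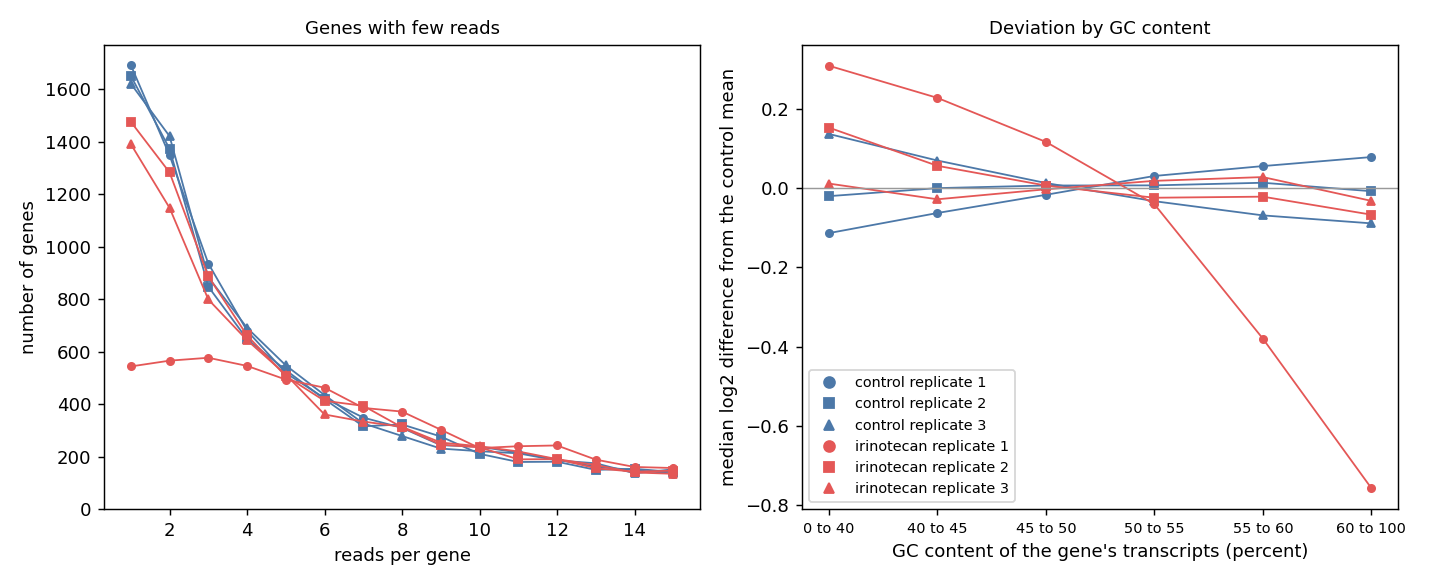
Left, number of genes (y axis) at each number of reads per gene from 1 to 15 (x axis), 1 line per library. Right, median log2 difference from the control mean (y axis) of the tested genes in 6 ranges of GC content in percent (x axis). Irinotecan replicate 1 has 544 genes at 1 read and reaches -0.757 above 60% GC.

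No single gene passed the threshold over all genes, and the values of 8 genes taken by the rule for named genes follow. S100a4, which encodes a calcium-binding protein, had 239.6 ± 38.7 normalized counts in controls and 717 ± 186 with irinotecan (SD, n = 3 each), a log2 fold change of 1.55 (SE 0.232). Ogn, a small leucine-rich proteoglycan of the matrix, had a mean of 2184 ± 377 against 4338 ± 420 (SE of the log2 fold change 0.161). The guanylate-binding proteins Gbp2b and Gbp2, interferon-inducible GTPases, had log2 fold changes of 1.34 (SE 0.216) and 1.24 (SE 0.212). Values were lower with irinotecan for Igfbp3, which binds insulin-like growth factors (3907 ± 526 against 2125 ± 124), for the circadian repressor Nr1d1 (477.6 ± 61.8 against 240.0 ± 16.3), for the basement membrane protein Nid2 (383.3 ± 28.6 against 204.4 ± 17.6), and for the macrophage scavenger receptor Cd163 (373.2 ± 74.0 against 171.1 ± 17.3). For these 4 genes the log2 fold changes were -0.87 (SE 0.141), -0.98 (SE 0.165), -0.90 (SE 0.162) and -1.10 (SE 0.204). In each of the 8 genes the irinotecan libraries all lay on one side of the controls, which was part of the rule that picked them, and the limma adjusted p was 0.662.

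On GRCm38, S100a4 lies on chromosome 3 from 90603771 to 90606045, and Gbp2b (142594847 to 142619179) and Gbp2 (142620602 to 142638008) are neighbours on chromosome 3. Ogn lies on chromosome 13 from 49608046 to 49624501. Igfbp3 (7206086 to 7213923) and Nr1d1 (98767932 to 98775333) lie on chromosome 11. Nid2 lies on chromosome 14 from 19751265 to 19811787 and Cd163 on chromosome 6 from 124304656 to 124330527. The values are normalized read counts per annotated gene. Which parts of each span were counted is not given in the sources used here.

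**Figure D2:**
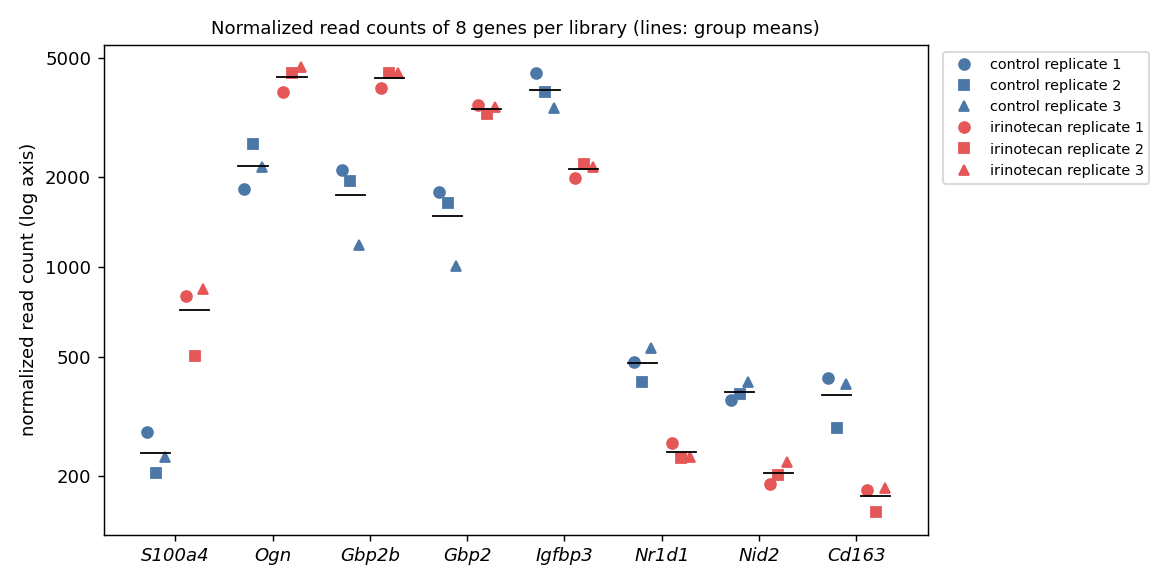
Normalized read counts on a log axis (y axis) of the 8 genes (x axis), with 1 point per library and a line at each group mean. The S100a4 mean is 239.6 in controls and 717 with irinotecan, and the Cd163 mean is 373.2 and 171.1.

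Over all 14639 genes limma called 0 genes higher and 0 lower with irinotecan. An unadjusted p under 0.05 was found for 844 genes (393 higher and 451 lower), where evenly spread p-values would give about 732. The other splits of the 6 libraries gave 98 to 746 such genes by the same test. On the recovered reads, edgeR and limma-voom also called 0 genes in either direction, whereas DESeq2 called 28 higher and 19 lower. The authors' deposited table has the same 28 and 19 genes at an adjusted p under 0.05. The limma log2 fold change had the same sign for all 47. Both matches come from the same libraries, so neither is independent support. In the authors' deposited table the 28 higher genes include Gbp2b, Gbp2, Gbp3, Gbp7, Irgm1, Irgm2, Iigp1 and the p53 target Trp53inp1, along with copies of ribosomal protein genes. The 19 lower genes in the authors' deposited table include the haem oxygenase Hmox1 (log2 fold change -1.20), the iron exporter Slc40a1 (-1.84), Cd163 (-1.13) and the heat shock gene Hspa1a (-1.96). Genes named here from that table outside the rule for named genes were chosen after their values were seen. Of the 28 higher genes, 6 belong to the list of interferon-gamma-induced genes (Fisher's exact test, two-sided, odds ratio 179, 95% interval 54 to 519, adjusted p = 2.08e-11 over 2 lists, background 13984 genes) and 0 to the interferon-stimulated list (exact p = 1). This test was not planned, and it covers 2 of the 40 lists. Fisher's test treats genes as independent, and the interferon-gamma list as a whole had an adjusted p = 0.353 with an estimated correlation. Without irinotecan replicate 1, limma called 2 genes higher, Ogn and the ribosomal protein gene Rps29, and DESeq2 called 74 higher and 77 lower, among them 38 of the 47.

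Of the 37 gene lists tested, camera ranked 8 higher and 12 lower with irinotecan than the other genes. All 20 calls were lost with an estimated correlation, where each list was again compared with the other genes and the smallest adjusted p was 0.353. With fry, which instead tests a list against no change, the smallest adjusted p was 0.177. No list member passed the limma threshold over all genes, and 29 passed when adjusted over the list alone, with Atf3 counted in both lists that hold it.

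Interferon-responsive genes were ranked higher. Of the 32 interferon-stimulated genes, which encode antiviral proteins, 30 had a positive log2 fold change, with a median of 0.49 (camera adjusted p = 1.84e-13; adjusted p = 0.353 with an estimated correlation), and 0 passed adjusted over the list alone. The medians per library relative to the control mean were -0.0018, 0.35 and -0.37 in the controls and 0.39, 0.59 and 0.51 with irinotecan. Without control replicate 3 the median was 0.29 (camera adjusted p = 3.38e-08). Parp14 had a log2 fold change of 0.83 (SE 0.2), Herc6 of 0.66 (SE 0.194) and the transcription factor Irf7 of 0.78 (SE 0.245). Irf7 was at 0.48 without control replicate 3, and Herc6 at 0.42 with the GC and length trend removed. Of the 27 interferon-gamma-induced genes, 22 had a positive log2 fold change, with a median of 0.57 (camera adjusted p = 2.99e-08; adjusted p = 0.353 with an estimated correlation). Adjusted over the list alone, 14 passed, of which 12 rose, among them Gbp2, Irgm1 (log2 fold change 1.09, SE 0.207) and Gbp7 (0.94, SE 0.183), while Nos2, the inducible nitric oxide synthase (-0.78, SE 0.230), and Upp1, a uridine phosphorylase (-0.47, SE 0.165), fell. The medians per library were 0.224, 0.207 and -0.481 in the controls and 0.232, 0.818 and 1.04 with irinotecan. Irinotecan replicate 1 thus lay close to control replicates 1 and 2. The list median was 0.90 without irinotecan replicate 1.

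The MHC class I list, for peptide loading and display to CD8 T cells, was ranked higher with a median of 0.21 over 21 genes (camera adjusted p = 0.00188; adjusted p = 0.606 with an estimated correlation). Its medians per library were 0.135, 0.0958 and -0.195 in the controls and -0.194, 0.283 and 0.428 with irinotecan, so irinotecan replicate 1 lay at the lowest control. The peptide transporter Tap2 had a log2 fold change of 0.69 (SE 0.171), the immunoproteasome subunit Psmb8 of 0.53 (SE 0.161) and Nlrc5, a transactivator of these genes, of 0.44 (SE 0.156). This call was lost without control replicate 3 (median 0.135, adjusted p = 0.051), irinotecan replicate 2 (0.167, adjusted p = 0.0518) or irinotecan replicate 3 (0.1, adjusted p = 0.179), and without irinotecan replicate 1 the median was 0.36. It was 0.32 with the TMM scaling or with the GC and length trend removed, and 0.33 with estimated library weights. Cytotoxic effectors were ranked higher with a median of 0.56 over 18 genes, 13 of them positive (camera adjusted p = 0.00188; adjusted p = 0.353 with an estimated correlation). The granzymes Gzmd, Gzmc and Gzmf had log2 fold changes of 2.32 (SE 0.715), 1.49 (SE 0.454) and 1.87 (SE 0.660), the last being 1.24 without irinotecan replicate 2. Gzmd held 996.0 and 586.6 normalized counts in irinotecan replicates 1 and 2 and 115.5 in replicate 3, against 57.5 to 136.5 in controls. Without irinotecan replicate 2 the list did not pass (adjusted p = 0.142), and with no filter on low values its median was 0.32.

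T cell markers did not pass (camera adjusted p = 0.348; adjusted p = 0.835 with an estimated correlation). Their median log2 fold change over 23 genes was 0.04 while their mean was -0.0082, so median and mean differ in sign, and the camera direction was upward. The median per library was -0.57 in irinotecan replicate 1 and 0.48 and 0.14 in the other irinotecan libraries. Without irinotecan replicate 1 the list passed with a median of 0.32 (adjusted p = 0.00077), as it did with estimated library weights (0.00213), and without control replicate 3 or irinotecan replicate 2 its direction turned (-0.07 and -0.22). The T cell receptor constant gene Trbc1 had 39.2 ± 9.4 normalized counts in controls and 74.8 ± 6.7 with irinotecan (log2 fold change 0.94, SE 0.289), the transcription factor Bcl11b a log2 fold change of 1.11 (SE 0.548), and the receptor subunit Cd3g of 0.67 (SE 0.361). Bcl11b was at 0.67 without irinotecan replicate 1, 0.71 with a pseudocount of 10 and 0.71 with estimated library weights. MHC class II genes also did not pass (adjusted p = 0.919, median -0.09 with an upward camera direction), and passed upward without irinotecan replicate 1 (adjusted p = 0.00077, median 0.43) and with estimated library weights (0.0141).

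**Figure D3:**
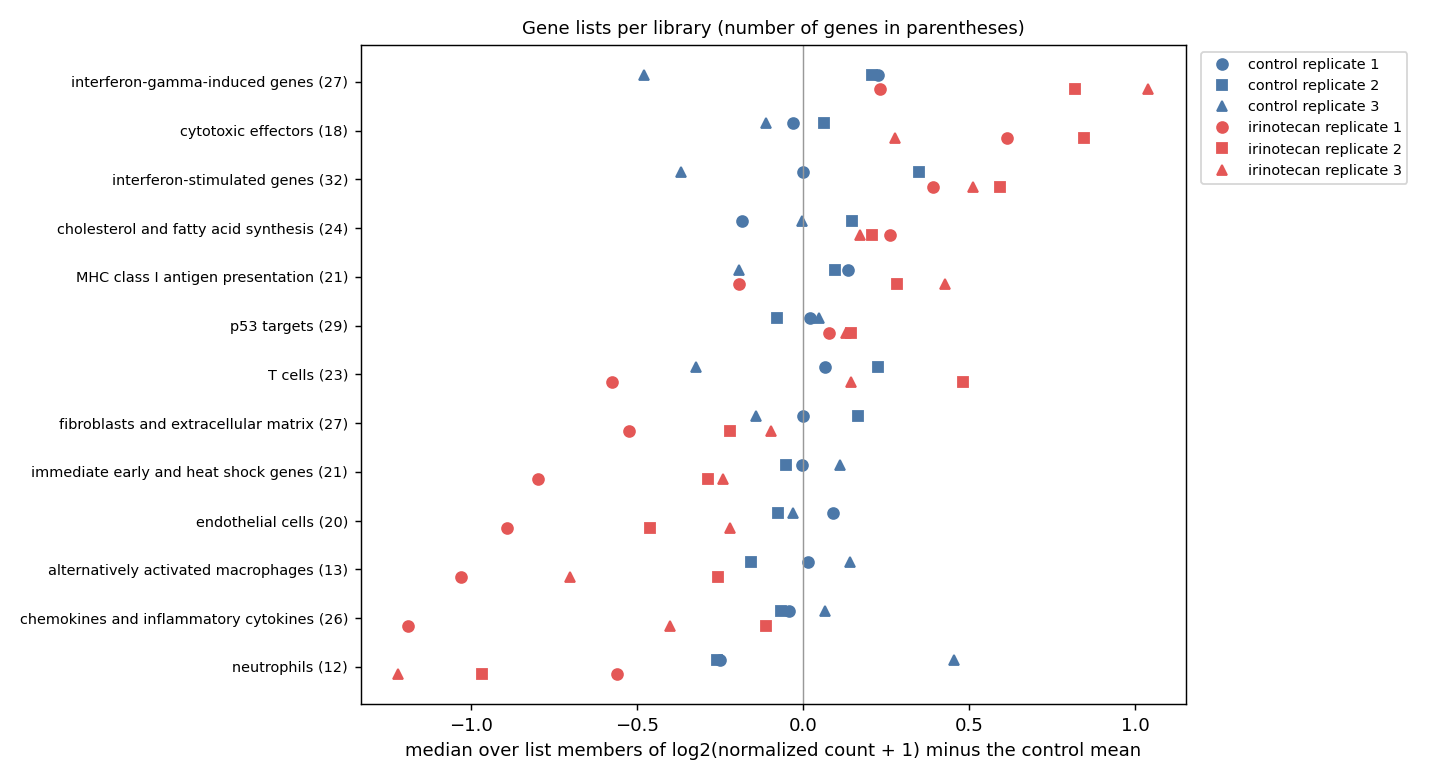
Median over the members of each of the 13 lists of log2(normalized count + 1) minus the control mean (x axis), 1 point per library, with the number of tested genes in parentheses (y axis). The neutrophil list lies at -0.561 to -1.22 with irinotecan and at -0.259 to 0.455 in controls.

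Myeloid lists were ranked lower. None of the 12 neutrophil genes tested, of 23 in the list, had a positive log2 fold change, with a median of -0.93 (camera adjusted p = 4.13e-06; adjusted p = 0.353 with an estimated correlation). With no filter on low values the median was -0.755 over 20 genes. Adjusted over the list alone, the iron-binding lipocalin Lcn2 (log2 fold change -1.43, SE 0.349) and the protease Mmp9 (-0.98, SE 0.255) fell, and the histidine decarboxylase Hdc had a value of -1.15 (SE 0.397). None of the 13 genes of alternatively activated macrophages tested, of 19 in the list, had a positive log2 fold change, with a median of -0.64 (camera adjusted p = 4.13e-06; adjusted p = 0.353 with an estimated correlation). Without the filter it was -0.589 over 18 genes. Cd163 and the mannose receptor Mrc1 (-0.74, SE 0.180) fell adjusted over the list alone, and osteopontin, Spp1, had a value of -0.64 (SE 0.241). The median of this list was -0.34 without irinotecan replicate 1 (adjusted p = 8.3e-05) and -0.39 with estimated library weights. Chemokines and inflammatory cytokines had a median of -0.68 over 26 genes, 3 of them positive (camera adjusted p = 9.56e-05; adjusted p = 0.568 with an estimated correlation), and did not pass without irinotecan replicate 1 (median -0.23, adjusted p = 0.185) or with estimated library weights (-0.24, adjusted p = 0.0698). With a pseudocount of 10 their median was -0.43. In this list the interferon-induced chemokine Cxcl11 had a log2 fold change of 0.98 (SE 0.249), while Il1b had -1.30 (SE 0.362) and the B cell chemokine Cxcl13 -1.86 (SE 0.522), or -1.09 with a pseudocount of 10. General macrophage and monocyte markers were ranked lower (median -0.33, camera adjusted p = 0.00501; adjusted p = 0.704 with an estimated correlation) with a median per library of -1.03 in irinotecan replicate 1 and of -0.00033 and 0.02 in the others. That call was lost without irinotecan replicate 1 (adjusted p = 0.745, with an upward camera direction), without control replicate 2 (0.115) or with estimated library weights (0.734).

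Vascular and stromal lists were ranked lower as well. Of the 20 endothelial genes 1 had a positive log2 fold change, with a median of -0.59 (camera adjusted p = 2.99e-08; adjusted p = 0.353 with an estimated correlation) and medians of -0.89, -0.46 and -0.22 in the irinotecan libraries. The adhesion genes Cdh5 and Pecam1 had log2 fold changes of -0.67 (SE 0.173) and -0.55 (SE 0.149), and the receptor Tie1 of -0.69 (SE 0.208). Fibroblast and extracellular matrix genes had a median of -0.34 over 27 genes (camera adjusted p = 0.00112; adjusted p = 0.353 with an estimated correlation), which was -0.17 without irinotecan replicate 1, -0.22 without control replicate 2 and -0.15 with estimated library weights. The collagen cross-linking enzyme Lox had a value of -0.72 (SE 0.186), Col12a1 of -1.08 (SE 0.301) and Postn of -0.91 (SE 0.275).

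Among stress and metabolic lists, immediate early and heat shock genes were ranked lower, 2 of 21 with a positive log2 fold change and a median of -0.42 (camera adjusted p = 7.64e-07; adjusted p = 0.353 with an estimated correlation). Hspa1a (-1.96, SE 0.439), Ier3 (-1.20, SE 0.282) and the transcription factor Atf3 (-1.26, SE 0.311) fell adjusted over the list alone. The median was -0.28 without irinotecan replicate 1 (adjusted p = 1.97e-07) and -0.23 with the GC and length trend removed (adjusted p = 5.31e-05). Cholesterol and fatty acid synthesis genes were ranked higher, 20 of 24 positive with a median of 0.23 (camera adjusted p = 2.38e-05; adjusted p = 0.353 with an estimated correlation), and with 0.15 without control replicate 1. Hmgcs1 and Lss, enzymes of sterol synthesis, had log2 fold changes of 0.67 (SE 0.181) and 0.37 (SE 0.134). The p53 target list was ranked higher by a small median of 0.09 over 29 genes, 20 of them positive (camera adjusted p = 0.0408; adjusted p = 0.353 with an estimated correlation). Trp53inp1 rose adjusted over the list alone (0.89, SE 0.178), Dglucy had a value of 0.70 (SE 0.181) and Ccng1 of 0.61 (SE 0.169). The p53 call was lost with quantile normalization (median 0.126, adjusted p = 0.0578) and without control replicate 2 (0.0545, adjusted p = 0.312), irinotecan replicate 2 (0.0538, adjusted p = 0.207) or irinotecan replicate 3 (0.11, adjusted p = 0.162). Its median was 0.137 without irinotecan replicate 1.

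Genes of the fixed panel gave mixed values, and none passed. Top1, the drug target, had 2306 ± 111 normalized counts in controls and 2343 ± 262 with irinotecan (log2 fold change 0.02, SE 0.134), and its sign turned with quantile normalization (-0.03). Cd8a had 135.2 ± 34.1 and 142.9 ± 51.9 normalized counts (0.04, SE 0.309), and Gzmb 166.1 ± 35.6 and 319.7 ± 148.9 (0.86, SE 0.328). The checkpoint ligand gene Cd274 had a log2 fold change of 0.48 (SE 0.166), the chemokine gene Cxcl9 of 0.44 (SE 0.508), the cell cycle inhibitor gene Cdkn1a of 0.20 (SE 0.155) and the proliferation marker gene Mki67 of 0.22 (SE 0.152). Cxcl9 had 301.9 normalized counts in irinotecan replicate 1 and 1114.4 and 1214.2 in the others, and its log2 fold change ranged from 0.08 to 1.08 when each library was left out in turn. The same range was -0.22 to 0.30 for Cd8a, 0.51 to 1.15 for Gzmb, 0.094 to 0.32 for Cdkn1a and 0.12 to 0.31 for Mki67, which was at 0.072 with the GC and length trend removed. Cd274 rose adjusted over the interferon-gamma list alone. Ifng lay below the filter, with 4.67, 4.18 and 5.81 normalized counts in controls and 0, 8.67 and 19.3 with irinotecan.

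Camera called 7 further lists. Skeletal muscle (adjusted p = 0.00301) and mitosis genes (0.00496) were ranked higher. The unfolded protein and integrated stress response (0.00199), ribosomal proteins (0.00496), the TGF-beta response (0.00501), mast cells and eosinophils (0.0174) and dendritic cells (0.0487) were ranked lower. With an estimated correlation the adjusted p was 0.611 for skeletal muscle, 0.606 for mitosis, 0.353 for the unfolded protein and TGF-beta lists, 0.665 for ribosomal proteins, 0.596 for mast cells and 0.723 for dendritic cells. Skeletal muscle, at a median of 0.52, was lost without control replicate 2 (median 0.13, adjusted p = 0.502) or irinotecan replicate 3 (0.295, adjusted p = 0.112), and its median was 1.09 without control replicate 1, 1.02 without irinotecan replicate 2 and 0.35 with a pseudocount of 10. Mitosis, at 0.0863, was lost without control replicate 3 (median 0.0266, adjusted p = 0.0887), without irinotecan replicate 3 (0.0377, adjusted p = 0.196) or with the GC and length trend removed (0.0412, adjusted p = 0.135), and its median was 0.157 without irinotecan replicate 1 and 0.0437 with quantile normalization. Ribosomal proteins, at -0.176, were lost with the GC and length trend removed (median -0.139, adjusted p = 0.134), and their median was -0.0564 without irinotecan replicate 1 (adjusted p = 0.0399) and -0.0986 with estimated library weights. The TGF-beta response, at -0.34, was lost without irinotecan replicate 2 (median -0.28, adjusted p = 0.0813) and had a median of -0.18 without irinotecan replicate 1. The unfolded protein response, at -0.18, was lost without irinotecan replicate 3 (median -0.13, adjusted p = 0.0712). Mast cells, at -0.55, were lost without control replicate 1 (median -0.224, adjusted p = 0.365) or irinotecan replicate 1 (-0.0732, adjusted p = 0.15), and their median was -0.255 with estimated library weights.

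Dendritic cells, at a median of -0.41, were lost without control replicate 1 (median -0.32, adjusted p = 0.159) or control replicate 2 (-0.43, adjusted p = 0.115). Without irinotecan replicate 1 their direction turned upward (0.053, adjusted p = 0.403), and their median was -0.62 without irinotecan replicate 2 and -0.68 without irinotecan replicate 3. The call was also lost with the GC and length trend removed (median -0.435, adjusted p = 0.104), quantile normalization (-0.31, adjusted p = 0.0765), the TMM scaling (-0.23, adjusted p = 0.0682), estimated library weights (-0.009, adjusted p = 0.959), a pseudocount of 10 (-0.30, adjusted p = 0.0641) and protein-coding genes only (-0.41, adjusted p = 0.0641).

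The remaining lists did not pass, with camera adjusted p from 0.0795 for NK cells to 0.919. They include B cells, regulatory T cells, DNA replication, DNA repair, apoptosis, hypoxia, oxidative phosphorylation, DNA sensing and irinotecan activation. Without irinotecan replicate 1, hypoxia and glycolysis genes passed downward (adjusted p = 3.53e-06, median -0.20 against -0.088), and NK cells (0.00173) and DNA sensing (0.0161) upward, as all 3 did with estimated library weights (6.78e-05, 0.00213 and 0.0426). Hypoxia also passed without control replicate 1 (0.0215) or 3 (0.00678), and NK cells without control replicate 2 (0.0205), with quantile normalization (0.0435) or with no filter (0.0379). B cells passed downward without control replicate 3 (0.0245), without irinotecan replicate 3 (0.0326) or with no filter (0.00185), and adipocytes without irinotecan replicate 3 (0.0469) or with no filter (0.0484). DNA replication passed downward without control replicate 2 (0.0261), erythroid genes upward without control replicate 3 (0.0196), and mitochondrially encoded genes downward without irinotecan replicate 2 (0.0251). Skin, histone and nerve lists had fewer than 5 tested members and were not tested.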

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

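The count of genes past the threshold depended on the tool and on irinotecan replicate 1. Against 0 higher and 0 lower with limma, DESeq2 on the recovered reads called 28 and 19, of which 47 are shared with the authors' deposited calls, where limma shares 0. Alternatives chosen after seeing the data called 5 higher (edgeR without irinotecan replicate 1), 74 higher and 77 lower (DESeq2 without it), and 30 higher and 22 lower (limma with estimated library weights, in which that library weighed 0.127 and the others 1.19 to 1.88). Leaving out each library in turn, limma called 0 to 2 genes higher and 0 lower. In the simulation 19.5% of the DESeq2 calls and 4.88% of the limma calls were unchanged genes, or 9.79% and 4.58% with the dispersions found without irinotecan replicate 1. The simulation drew genes independently with 1 dispersion for all libraries, whereas in the data irinotecan replicate 1 stands apart. These shares therefore need not hold for the real calls. Camera called 4 to 12 lists higher and 9 to 14 lower when each library was left out, against 8 and 12. It called 0 and 0 with an estimated correlation, and fry, which tests against no change, also gave 0 and 0. The 2 camera runs differed in whether the inter-gene correlation was preset at 0.01 or estimated. That setting also changes the degrees of freedom that camera uses. The calls thus rest on the preset run, and the 2 parts of the change were not separated. Why fry called none was not tested. Without irinotecan replicate 1, 16 of the 20 lists remained and 5 others passed. The shared replicate numbers gave no sign of pairing. Deviations of same-numbered libraries correlated at -0.11, -0.0087 and -0.21, against -0.05 to 0.16 for libraries with unlike numbers. With so few libraries this check cannot exclude pairing. With the replicate number as a block, limma called 0 genes and camera 7 lists higher and 12 lower, and the p53 list did not pass (adjusted p = 0.0764). Of the described lists and named genes, 3 changed direction. T cell markers, at -0.04 over protein-coding genes only, ranged from -0.22 to 0.32, Cd8a from -0.22 to 0.30 and Top1 from -0.054 to 0.108 when each library was left out, and Top1 was -0.030 with quantile normalization and -0.19 with the GC and length trend removed, a correction also chosen after seeing the data. The other 12 lists described in detail kept their direction under each alternative run. So did the other named genes that were tested, in each alternative that held them, while Ifng lay below the filter. Of the 8 other lists that passed, 2 turned upward without irinotecan replicate 1, macrophages and monocytes (median -0.0026) and dendritic cells (0.053). Of the 16 other lists that did not pass, 11 turned at least once, among them MHC class II, at -0.37 without control replicate 3 and 0.43 without irinotecan replicate 1. Depth was alike, 13940650 to 15656894 reads, so genes with few reads have the largest counting error in each library.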

Other observations

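Chosen after the result was seen were the tests of few RNA molecules, of T cells and of the spread between tumours. So were those of red blood cells and of the ribosomal copies. The same holds for edgeR with TMM, limma with estimated library weights and the removal of the GC and length trend. It also holds for every alternative without irinotecan replicate 1 that used DESeq2 or edgeR. Fisher's test of the deposited calls was not planned either. The bounds for T cells, red blood cells and reads shared with ribosomal copies were also changed after their first outcome was seen, and each of these explanations is left open. The genes in the next paragraph were also picked after their values were seen.

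Some genes outside the described lists had large values. The clock repressor gene Ciart had 194.8 ± 16.7 normalized counts in controls and 103.3 ± 25.9 with irinotecan (log2 fold change -0.94, SE 0.237), and with Nr1d1 it fell adjusted over the circadian list alone, while the list as a whole did not pass (camera adjusted p = 0.537). The peptide hormone gene Apln had 1190 ± 169 and 722 ± 13 (log2 fold change -0.71, SE 0.143). A2m had 125.3 normalized counts in irinotecan replicate 1 and 0 to 2.80 in the other 5 libraries, and the long gene Ahnak had 116370 against 33490 to 44165.

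Irinotecan replicate 1 differed from the other libraries in shape. A GC and length trend alone is argued against: after it was removed, the SD of this library's deviations was still 1.93 times the highest SD among the others, against 2.06 times before. Few RNA molecules behind the library may contribute, since 46.92% of the genes with a mean of 2 to 5 in the other libraries were at 0 reads in it, against 20.17% to 28.6% for the others treated alike. That share largely restates the smaller number of genes with reads in this library, so it is not separate evidence. Fewer host cells in that tumour stay open too, since 33 abundant macrophage, dendritic cell, MHC class II and fibroblast genes lay at a median of -0.696 after the trend was removed, against -0.16 to 0.142 in the other libraries. Before the trend was removed, the 8 tested epithelial tumour cell genes had a median of -1.11 in it, against -0.218 to 0.0823 in the others. Lower values were thus not limited to host genes. Few RNA molecules and fewer host cells are not exclusive explanations, and the design offers no group to set them against.

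The higher ranking of interferon lists is argued not to be a GC and length trend, since the interferon-stimulated median was 0.501 after its removal and 0.488 before, nor one control tumour with low expression alone, since it was 0.291 without control replicate 3. More T cells may contribute and stay open: their median was 0.0438 (SE of the members' mean 0.131) and 0.316 without irinotecan replicate 1 (SE 0.061), where the interferon-stimulated median was 0.588. A T cell median below the interferon median was first taken to exclude them, and that bound was dropped after the result was seen, because added T cells need not raise both lists alike. Spread between tumours cannot be told apart from treatment, because the exact permutation test of the library medians, two-sided, gave p = 0.1, the smallest that 3 against 3 allows. An effect of irinotecan on interferon signalling remains an open hypothesis.

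Among the deposited calls, copies of ribosomal protein genes stood out. Rps27rt, Rps13-ps2, Rpl9-ps6 and Rpl10-ps3 were higher, whereas Rpl34-ps1 was lower (log2 fold change -0.80). Reads moving between parent and copy may contribute and cannot be told apart from a real change. In 4 of 5 pairs the copy held 0.384% to 5.79% of the summed control reads, so the sum follows the parent and decides nothing. Rps27rt held 31.9%, and there parent (log2 fold change 0.34), copy (1.04) and sum (0.607, SE 0.237) were all higher, which goes against a transfer alone but lies within its error of the bound set for excluding it. Recovery of short transcripts as the whole cause is argued against, since 29 protein-coding genes of 200 to 500 bases had a median log2 fold change of -0.108 (quartiles -0.587 and 0.235) and 73 genes of up to 200 bases one of -0.0362. The mitochondrial tRNA genes go with it, however. Over 8 of them the median was 0.507 (quartiles -0.311 and 1.2), with 6 positive, and mt-Tp (1.56) and mt-Tc (2.02) were higher in the authors' deposited table. No biological explanation was tested.

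Cd163, Hmox1 and Slc40a1 handle haemoglobin and iron, and fewer red blood cells in treated tumours was a candidate explanation for their lower values. It stays open: summed haemoglobin counts ranged from 408.8 to 2563.1 in controls and reached 2016.6 with irinotecan, a log2 difference of 0.53 (SE 0.994), within the spread between libraries. The granzyme cluster (Gzmc to Gzmg, 5 genes) had medians of 2.6 and 2.84 above the control mean in irinotecan replicates 1 and 2 and 0.315 in replicate 3. Whether cytotoxic lymphocytes may account for this was tested, with bounds set before the result was seen, as a rank correlation with Cd3e, Cd8a, Ncr1 and Prf1 over the 6 libraries, the only relation of this kind computed. It was left open: Spearman's rho was 0.429 (exact permutation p = 0.419), Pearson's r was 0.689 (exact permutation p = 0.163), and r was -0.949 without the 2 libraries farthest from the granzyme median. Those are irinotecan replicates 1 and 2, which hold the high values in question, so r rests on them and the other 4 libraries cannot decide.

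For chance groupings of the 6 libraries, 10 splits are too few for a share under 0.05. The real split gave 0 genes and the highest of the others 0, so 10 of 10 gave as many. With 0 genes in the real split no other outcome was possible, so this decides nothing. At an unadjusted p under 0.05 by limma the real split gave the most genes, 844, and the others 98 to 746. For lists, the real split gave 20 and the highest of the others 19, so 1 of 10 gave as many.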
